A study of Homo sapiens with 12 samples.

How the data were processed

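Gene expression was measured by RNA sequencing in RPE1, a line of human retinal pigment epithelial cells immortalised with telomerase. The 12 libraries formed 4 groups of 3, per the labels: control cells and cells in which the proximal polyadenylation site (pPAS) of MRE11 had been knocked out, each on day 3 and on day 6. The control titles name eCas9, a Cas9 variant engineered for higher specificity. Per the labels' protocols, polyadenylated RNA was captured with oligo(dT) beads, fragmented and primed with random hexamers, and no strand-marking step is named. The labels do not say from which event the days were counted, whether the knockout cells were a clone or a pool, or whether replicates were separate cultures.

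Per the submitters' processing notes, the authors used Bowtie2, STAR, RSEM and DESeq2 with the hg38 build, and the notes give neither versions nor the role of each tool. RSEM expected counts, which are estimated counts that need not be whole, were deposited for 60676 genes in each library. The deposited series table held the same expected counts with their decimals dropped, which was so for 100% of its cells. Its whole numbers were used for the count tests, and 0 sample columns were left unused. TPM values, deposited for each library, are counts divided by effective length and scaled by RSEM to a common sum over transcripts. They entered an alternative test only, and group means are given for MRE11. FPKM values were also deposited by the authors and were not used here. The deposited length of a gene was RSEM's mean transcript length in bases, weighted by the abundance of the gene's transcripts, and the effective length was the same after a fragment length correction. Because the table does not record how multi-mapping reads were shared out, RSEM could split reads between near-identical genes, and values of such genes are uncertain. Counting was not stated to use strand, so reads of overlapping antisense genes could not be told apart.

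Gene positions, biotypes, GC content and transcript lengths came from GENCODE release 29 on GRCh38, which held 96.42% of the gene identifiers. Library totals ranged from 20.63e6 to 21.67e6 counts. A count of 0 was bounded with a floor of 3 counts over the 3 libraries of a group, and ratios with 1 to 3 counts in a group carry an exact 95% binomial interval. Intervals and floors cover counting error only, since the protocol names a PCR step and no molecular identifiers.

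Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 14924, and library composition was adjusted by TMM factors. A robust quasi-likelihood model with the 4 group means was fitted to all 12 libraries, with 8 residual degrees of freedom and a common biological coefficient of variation of 0.065. Two-sided tests were made of knockout against control on day 3 and on day 6, of the difference between these effects, and of day 6 against day 3 in each genotype. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are approximate, being the absolute log2 fold change divided by the square root of the F statistic. For genes with few counts in a group they can be smaller than the counting error.

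The design, the gene lists, the naming rule and most of the alternative settings were fixed before the data were examined. There were 27 lists of pathways, complexes and neighbouring genes, and 5 lists of markers of mature pigment epithelium, fibroblasts, keratin-rich epithelium, a neural-like kidney line and blood cells. Lists with at least 3 tested members were tested with camera in edgeR, using a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry in limma 3.58.1. Weighted transcript length was tested on the log2 scale with limma for 9875 genes with a mean expected count of at least 100. Named genes were the 12 largest rises and 12 largest falls of each knockout comparison among called genes that had a symbol, averaged at least 5 CPM over the comparison's libraries and showed no overlap between the 3 knockout and 3 control values. For the difference between days and for each change with time, 5 rises and 5 falls were named. For lists, up to 4 members with the smallest p were named. MRE11, RAD50, NBN, ANKRD49, CDKN1A and MDM2 were always named, and for weighted length MRE11 and the 5 genes with the smallest p. Genes within 1 Mb of MRE11 and genes nearly absent from a group were named after their values had been seen. Results of a few genes under these rules are not reported here.

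Both tests were tried on simulated data with 200 changed genes, built from the real library sizes, gene means and spreads. For the day 3 comparison, edgeR recovered 79% of genes changed 1.5-fold, 94% of those changed 2-fold and 98.2% of those changed 4-fold among 14655 genes, and 8.1% of its calls were false. For day 6 it recovered 83.1%, 95.9% and 97% at the same folds among 14644 genes, with 5.6% false calls. On each day camera recovered the 1 list shifted by 1.3-fold and called 0 others, among 14642 genes for day 3 and 14636 for day 6. The length test recovered 83% of genes changed by 0.5 on the log2 scale on day 3 and 79% on day 6 among 9875 genes, with 5.7% and 4.8% of its calls false. Simulated genes varied independently of each other, and only 200 genes or 1 list changed. These rates therefore need not hold for real data, where genes vary together and far more of them changed.

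The alternative settings fixed in this way were DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 0.5), RLE size factors, library totals without TMM, other count filters, rounding of the expected counts, glmTreat against a 1.2-fold change, stricter thresholds, the replicate number as a block, each day fitted alone, other length settings and leaving out each library in turn. Correction for GC content and length, leaving out the 100 most abundant genes and leaving out day 6 control 1 with day 6 knockout 3 were added after the data had been seen.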

Results

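The study knocked out the proximal polyadenylation site of MRE11 in RPE1 cells and asked which genes were then deregulated. RNA from 3 control and 3 knockout libraries was compared on day 3 and again on day 6. Library totals lay between 20.63e6 and 21.67e6 counts. A count was found for 20104 ± 96.1 genes (SD, n = 3) in control and 19922 ± 80.9 in knockout libraries on day 3, and for 20274 ± 69.4 and 18201 ± 398 on day 6. The TMM factors, which adjust for library composition, were 1.14 to 1.17 on day 3 and 0.981 to 0.99 in day 6 controls, against 0.752 to 0.781 in day 6 knockout libraries. In a principal component analysis the 12 libraries formed 4 separate groups, with 45.9% of the variance on the first component and 33.6% on the second. FN1, which encodes fibronectin, alone took 1.18% ± 0.054 (SD) of control and 1.75% ± 0.121 of knockout counts on day 3, and 4.33% ± 0.384 and 5.08% ± 0.333 on day 6. Since the labels do not say whether replicates were separate cultures, the p-values measure only the spread between these samples, which may be technical. Below, values after ± are standard errors of log2 fold changes unless SD is named, and CPM values are counts scaled to a common library size with the TMM factors.

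MRE11 encodes the nuclease of the MRE11-RAD50-NBN complex that senses DNA double-strand breaks. It lies on the minus strand of chromosome 11 from 94415578 to 94493908 (GRCh38). Its counts were 450, 339 and 426 in day 3 controls and 275, 318 and 284 in day 3 knockouts. On day 6 they were 161, 155 and 136 in controls and 75, 111 and 77 in knockouts. MRE11 fell in the knockout by 0.43 ± 0.112 on day 3 (edgeR, Benjamini-Hochberg adjusted p = 0.00454) and by 0.37 ± 0.145 on day 6 (edgeR, Benjamini-Hochberg adjusted p = 0.0291). The day 6 call was lost with DESeq2 (log2 fold change -0.34, Benjamini-Hochberg adjusted p = 0.0561) and limma-voom (-0.38, Benjamini-Hochberg adjusted p = 0.0511), after GC and length correction, and when any 1 of 4 libraries was left out, of which leaving out day 6 knockout 1 gave the weakest value, -0.28. With library totals alone the day 6 value was -0.74, and with limma-trend on log2(TPM + 0.5) it was -0.89, each of them called. Its size thus depended on the scaling and, for TPM, also on the transcript length by which counts are divided. Mean TPM of MRE11 was 7.8 ± 0.95 in controls and 4.45 ± 0.46 in knockouts on day 3 (SD, n = 3). On day 6 it was 3.19 ± 1.25 and 1.43 ± 0.27 (SD, n = 3). MRE11 also fell from day 3 to day 6, by 1.21 ± 0.121 in controls and by 1.15 ± 0.135 in knockouts. Counts over the whole gene do not show whether the targeted site was removed.

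**Figure D1:**
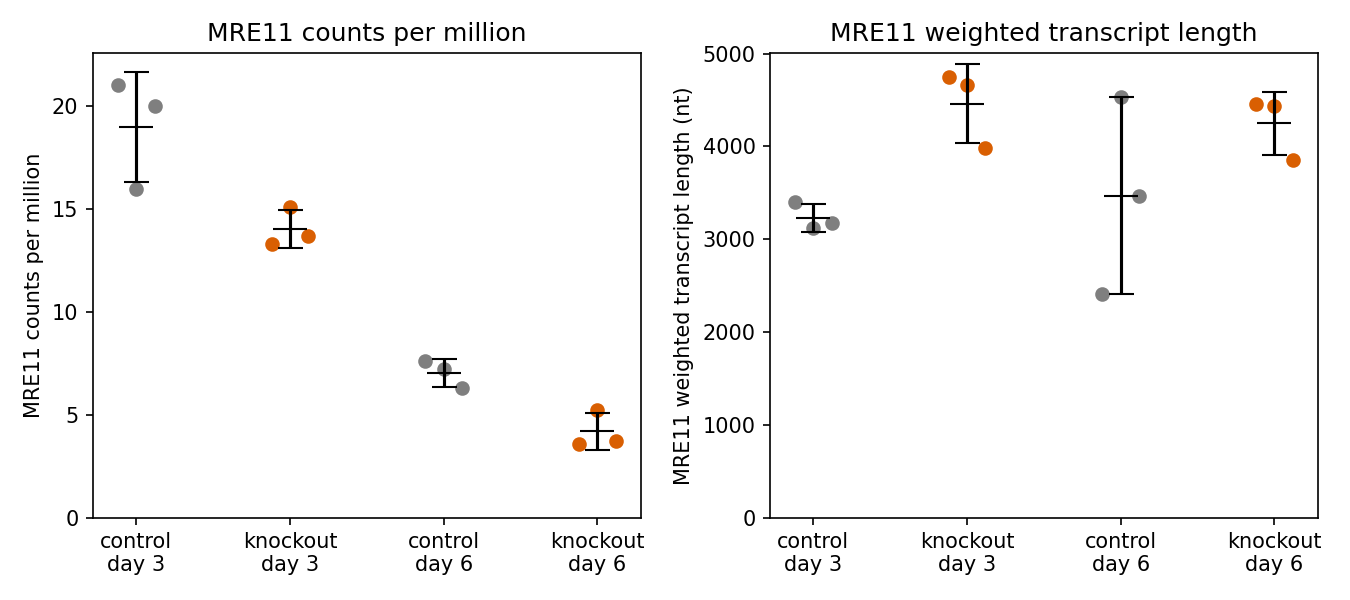
MRE11 CPM of the library total, without TMM factors (left), and weighted transcript length in nucleotides (right) in each of the 12 libraries, by genotype and day; points are libraries, and bars show the mean and SD of the 3 libraries of a group. Day 3 lengths of knockout and control libraries do not overlap.

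The annotated MRE11 transcripts end at different places. MRE11-201, of 6897 nucleotides, ends at position 94415578, whereas MRE11-202, MRE11-203 and MRE11-204, of 2588 to 2684 nucleotides, end between 94419866 and 94419878. The weighted transcript length of MRE11 was 3231 ± 148 nucleotides (SD, n = 3) in controls and 4463 ± 421 in knockouts on day 3, a log2 difference of 0.46 ± 0.193. The values did not overlap, which 10% of genes would show by chance with 3 against 3, and the smallest two-sided exact p of that design is 0.1. Taken alone, as a result fixed in advance, the MRE11 difference had an unadjusted p of 0.0398 (limma). Among 9875 genes it did not pass (limma, Benjamini-Hochberg adjusted p = 1). On day 6 the length was 3470 ± 1062 in controls and 4250 ± 343 in knockouts (SD, n = 3), and did not pass (limma, unadjusted p = 0.115, Benjamini-Hochberg adjusted p = 0.393). One gene, EMC10, changed its weighted length on day 3 by -0.34 ± 0.0136, with knockout counts near 0, and 442 genes were under an unadjusted p of 0.05. ANKH, ANTXR1, MIAT and RNF216 had the next smallest p on day 3, with log2 differences of 0.59, 0.08, 0.63 and 0.08, and did not pass. On day 6, 518 genes changed their weighted length, 72 longer and 446 shorter in the knockout. PVR, which encodes the poliovirus receptor, went from 3160 to 2463 nucleotides, LRRFIP1 from 3048 to 2006, DIDO1 from 5827 to 3554, FBXO32 from 1828 to 1163 and CSNK1G1 from 7508 to 3711. That count fell to 265 without day 6 control 1 and to 326 without day 6 control 2. The length effect differed between days for 134 genes, 7 of them longer and 127 shorter.

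RAD50 and NBN, the partners of MRE11, were measured at 68.1 and 30.3 CPM in day 3 controls. NBN fell by 0.33 ± 0.0846 on day 3, where limma-trend on log2(TPM + 0.5) did not call it (-0.30), and by 0.39 ± 0.104 on day 6. RAD50 fell by 0.34 ± 0.0733 on day 6, and its day 3 value of -0.12 ± 0.0692 did not pass. ANKRD49, which overlaps the 5′ end of MRE11 on the opposite strand, fell on day 6 by 0.58 ± 0.186 and had a day 3 value of 0.14 ± 0.159 that did not pass. The day 6 call of ANKRD49 was lost without day 6 control 1 (-0.47), without day 6 knockout 2 (-0.44) and without day 6 control 1 and knockout 3 together (-0.46). Reads of this gene and MRE11 could not be told apart where they overlap. MDM2, a ubiquitin ligase gene, fell on day 6 by 0.55 ± 0.0897, and its day 3 value of 0.10 ± 0.0819 did not pass. CDKN1A, the p21 cell cycle inhibitor, rose by 0.47 ± 0.0542 on day 3 and by 1.85 ± 0.0552 on day 6, from 333 ± 21.7 to 1199 ± 45.2 CPM (SD, n = 3) on the later day. Adjusted p for these calls was at most 0.00966 (edgeR, Benjamini-Hochberg).

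Of the 17 other tested genes within 1 Mb of MRE11, 2 rose and 2 fell on day 3, and 4 rose and 8 fell on day 6. GPR83, which encodes a G protein-coupled receptor, lies from 94377311 to 94401419 on the same strand, 14.2 kb beyond the annotated 3′ end of MRE11. Control libraries held 1, 1 and 0 counts of it on day 3 and 1, 1 and 1 on day 6. Knockout libraries held 95, 102 and 129 on day 3 and 35, 50 and 22 on day 6. The ratio of knockout to control was 168 (95% counting interval 46.1 to 1390) on day 3 and 47.4 (15.8 to 234) on day 6, and GPR83 rose on both days (edgeR, Benjamini-Hochberg adjusted p = 1.76e-11 and 1.48e-09). FUT4, a fucosyltransferase gene, fell by 2.58 ± 0.293 and 3.49 ± 0.353. SESN3, which encodes sestrin 3, was lower at a ratio of control to knockout of 15.5 (5.01 to 78) on day 3 and fell by 3.55 ± 0.392 on day 6; limma-trend on log2(TPM + 0.5) did not call it on day 3. ENDOD1 rose by 0.47 ± 0.057 and 0.70 ± 0.0556. On day 6 TAF1D rose by 0.92 ± 0.0792 and SRSF8 fell by 0.97 ± 0.0941. The list of neighbours fixed in advance had 16 tested members, of which 2 rose and 3 fell on day 3, and 4 rose and 8 fell on day 6, and it was not called (camera, Benjamini-Hochberg adjusted p = 0.773 and 0.858).

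**Figure D2:**
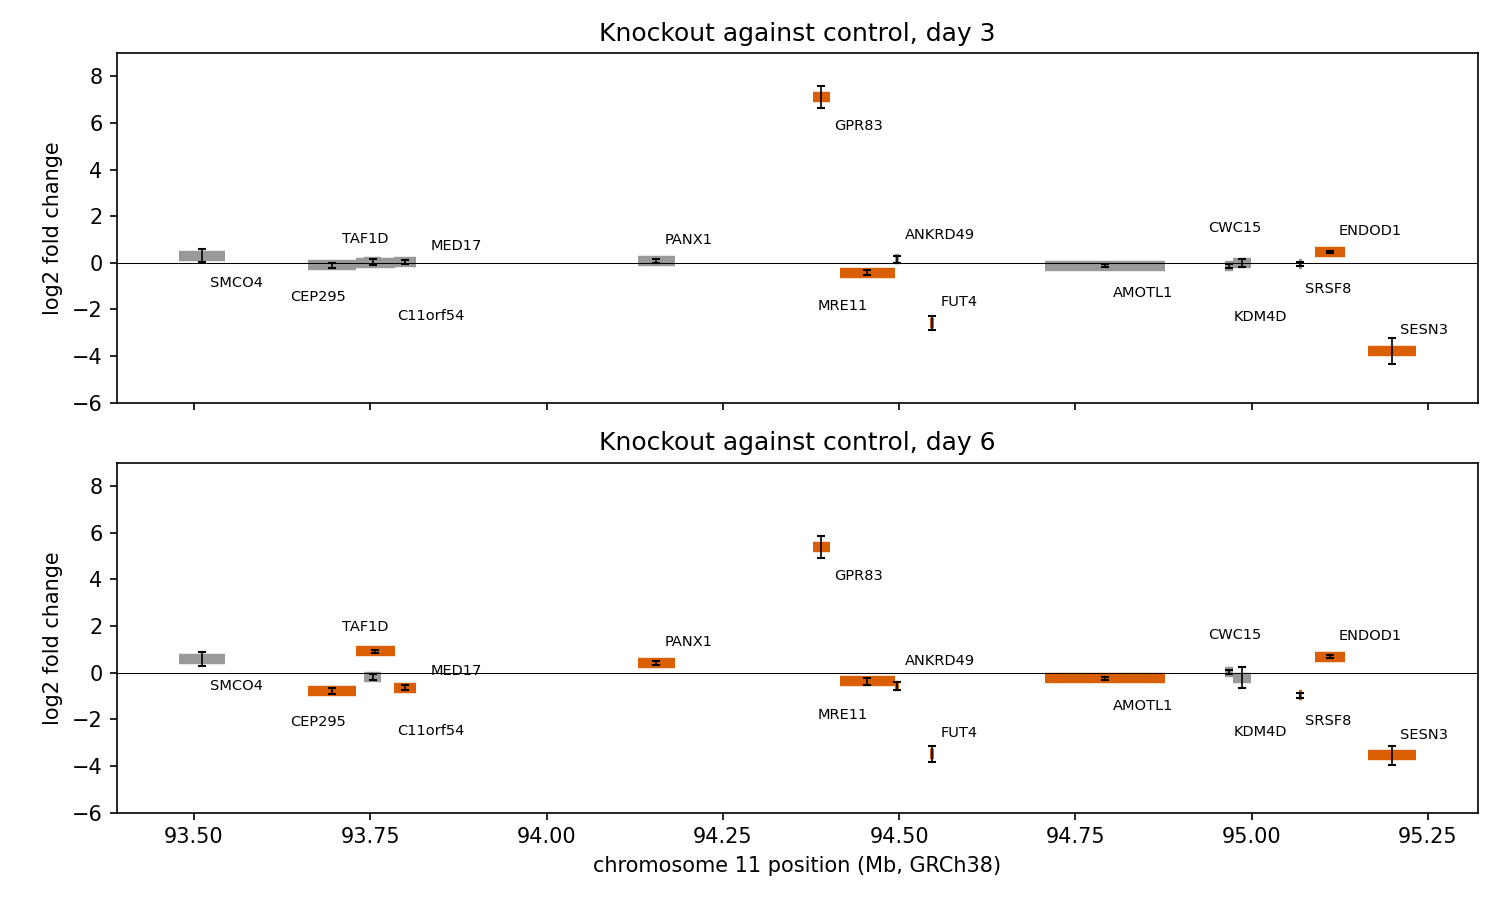
Fitted log2 fold change of knockout against control (vertical axis) for genes with a symbol within 1 Mb of MRE11 along chromosome 11 (position in Mb, GRCh38), on day 3 and day 6. Genes without a symbol are not drawn, although the text counts them. Each bar spans a gene, error bars are standard errors, and orange marks genes past an adjusted p of 0.05; GPR83 stands highest on both days.

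On day 3 the knockout cells had less RNA of inflammatory and secreted factors. CXCL8, which encodes interleukin-8, fell by 7.38 ± 0.147, from 149 ± 10.9 to 0.89 ± 0.245 CPM (SD, n = 3). C3, a complement component, fell by 5.60 ± 0.102, and lower values were also found for SERPINB2, a plasminogen activator inhibitor gene, at -4.04 ± 0.104, and IL1B, which encodes interleukin-1 beta, at -3.72 ± 0.101. TIMP3, an inhibitor of matrix metalloproteinases, fell by 7.08 ± 0.154, and IGFBP4 by 3.87 ± 0.17. Other large falls were those of EMC10, a subunit of the endoplasmic reticulum membrane complex, at -8.65 ± 0.182, TPD52 at -6.85 ± 0.412, and CPT1C at -4.97 ± 0.151. Knockout means were 0.08 CPM for EMC10, 0.11 for TPD52 and 0.17 for TIMP3, where these standard errors understate the counting error. GSTM1, at -6.14 ± 0.188, and MRPS21, at -5.83 ± 0.208, have near-identical relatives that make their counts uncertain. ZNF544 had 3 counts over the 3 knockout libraries and a ratio of control to knockout of 353 (95% counting interval 121 to 1720).

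Among the largest rises on day 3, HOXB6, a homeobox gene, rose by 3.29 ± 0.166 and PLXNA4, a semaphorin co-receptor, by 3.01 ± 0.112. G0S2, a lipolysis inhibitor, rose by 2.85 ± 0.0749, and KRT81, a hair keratin, by 2.66 ± 0.063, from 379 to 2385 CPM. Its related pseudogene KRT87P rose by 3.14 ± 0.318, and reads of this pair could be split in counting. IGFBP5 rose by 2.56 ± 0.0609, SAMD9 by 2.55 ± 0.149, FHL1 by 2.51 ± 0.0884 and WNK4, a kinase gene, by 2.43 ± 0.122. ZNF185, AMOT, which encodes angiomotin, and PTGFRN rose by 2.40 ± 0.0763, 2.32 ± 0.121 and 2.32 ± 0.0774. Adjusted p for the 24 genes of both directions was at most 5.92e-05 (edgeR, Benjamini-Hochberg). In all, 4841 of 14924 genes changed on day 3, 2066 higher and 2775 lower, and 920 of them at least 2-fold. Limma-trend on log2(TPM + 0.5) called 1876 higher and 1161 lower.

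Of the 29 lists with enough tested members, 9 were called on day 3. NF-kB targets and secreted inflammatory factors showed the largest shift, with 15 of 18 tested members lower, 2 higher and a median of -2.44. CXCL8 and IL1B were among them, with IL6 at -3.22 ± 0.143 and LIF at -1.17 ± 0.0547 (camera, Benjamini-Hochberg adjusted p = 1.19e-34, and adjusted p = 0.000894 with an estimated correlation). Of the cholesterol synthesis genes, 17 of 21 fell and 0 rose, at a median of -0.36. INSIG1, a sterol sensor, fell by 1.08 ± 0.0718, and DHCR7, which makes cholesterol from its last precursor, by 0.82 ± 0.0624 (camera, Benjamini-Hochberg adjusted p = 1.97e-05, and adjusted p = 0.00776 with an estimated correlation). Targets of YAP and TGF-beta rose in 15 of 19 cases and fell in 1, at a median of 0.49. The smooth muscle genes ACTA2, TAGLN and CNN1 rose by 1.75 ± 0.0627, 1.29 ± 0.0643 and 3.12 ± 0.201, and TGFB2 by 0.99 ± 0.0499 (camera, Benjamini-Hochberg adjusted p = 1.99e-13, and adjusted p = 0.00776 with an estimated correlation). Integrated stress response genes rose in 13 of 22 cases and fell in 2, at a median of 0.48. DDIT4, an inhibitor of mTOR signalling, rose by 1.32 ± 0.0704, the amino acid transporter gene SLC7A5 by 0.58 ± 0.0517 and VLDLR by 0.94 ± 0.0868, while STC2 fell by 0.51 ± 0.046 (camera, Benjamini-Hochberg adjusted p = 2.46e-06, and adjusted p = 0.00776 with an estimated correlation).

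The other 5 calls of day 3 were lost with an estimated correlation. Extracellular matrix genes rose in 18 of 26 cases and fell in 0, at a median of 0.58, and COL4A1, TGFBI and BGN rose by 1.32 ± 0.0523, 1.26 ± 0.052 and 1.28 ± 0.0635 (camera, Benjamini-Hochberg adjusted p = 4.87e-15, and adjusted p = 0.102 with an estimated correlation). DNA replication genes fell in 25 of 36 cases and rose in 0, at a median of -0.24, and the helicase subunit genes MCM3 and MCM4 fell by 0.40 ± 0.0518 and 0.32 ± 0.0515, and FEN1 by 0.44 ± 0.0731, of which limma-trend on log2(TPM + 0.5) did not call MCM4 (camera, Benjamini-Hochberg adjusted p = 0.00159, and adjusted p = 0.191 with an estimated correlation). Cytosolic ribosomal protein genes fell in 36 of 51 cases and rose in 0, at a median of -0.19, and RPL19 and RPL10 fell by 0.28 ± 0.0538 and 0.28 ± 0.0543 (camera, Benjamini-Hochberg adjusted p = 0.00157, and adjusted p = 0.529 with an estimated correlation). Unfolded protein response genes fell in 12 of 18 cases and rose in 2, at a median of -0.29, and the chaperone genes HYOU1, PDIA4 and CALR fell by 0.56 ± 0.058, 0.50 ± 0.0527 and 0.46 ± 0.0507 (camera, Benjamini-Hochberg adjusted p = 0.00645, and adjusted p = 0.191 with an estimated correlation). Glycolysis and hypoxia genes rose in 15 of 25 cases and fell in 5, at a median of 0.25. The hypoxia-responsive genes NDRG1 and CA9 rose by 1.45 ± 0.0769 and 1.40 ± 0.122, while the glycolytic genes TPI1 and ENO2 fell by 0.69 ± 0.0466 and 0.65 ± 0.0547 (camera, Benjamini-Hochberg adjusted p = 0.0124, and adjusted p = 0.212 with an estimated correlation). Adjusted over the list alone, the counts higher and lower were 2 and 16 for NF-kB targets, 0 and 17 for cholesterol synthesis, 16 and 1 for YAP and TGF-beta targets, 13 and 2 for the integrated stress response, 20 and 0 for matrix, 0 and 28 for DNA replication, 0 and 38 for ribosomal proteins, 2 and 13 for the unfolded protein response and 16 and 5 for glycolysis and hypoxia.

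**Figure D3:**
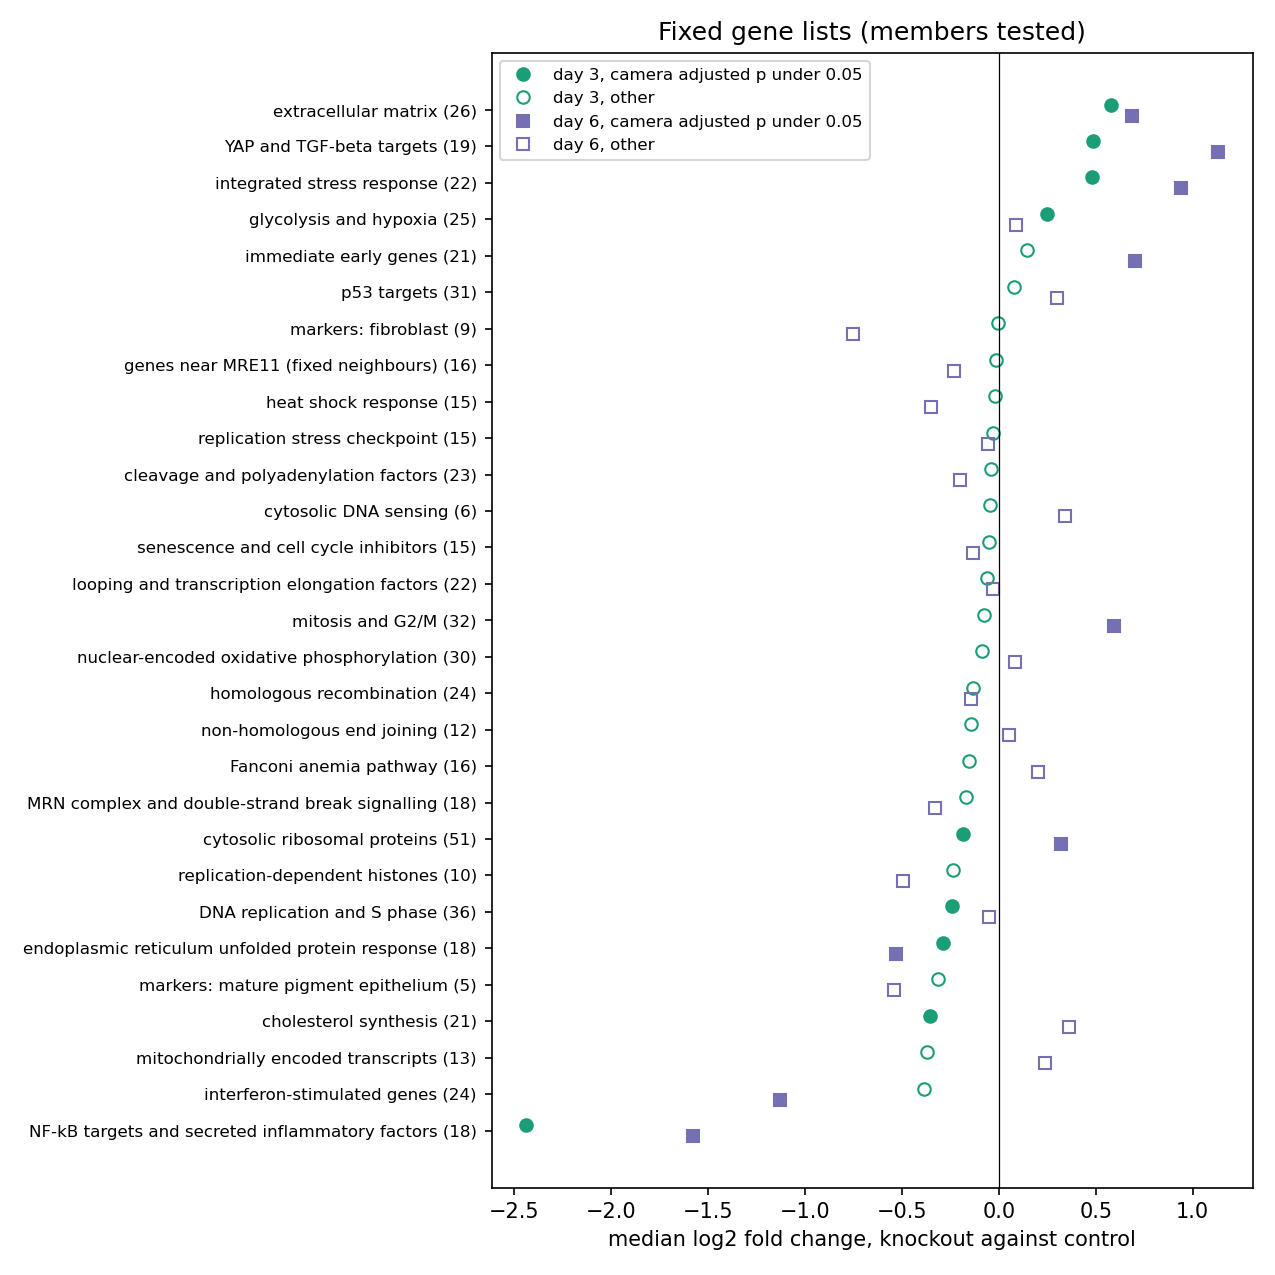
Median log2 fold change of knockout against control (horizontal axis) of each fixed gene list on day 3 (circles) and day 6 (squares), with the number of tested members in brackets; filled symbols have a camera adjusted p under 0.05, and no error bars are drawn. Only lists with at least 3 tested members are drawn, and among these NF-kB targets have the lowest medians, -2.44 on day 3 and -1.58 on day 6.

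DNA repair lists were not called on day 3. In the list of the MRN complex and break signalling, 6 of 18 genes fell and 0 rose, among them RBBP8, which encodes the resection factor CtIP, by 0.32 ± 0.0648, not called with limma-trend on log2(TPM + 0.5). Of 24 homologous recombination genes, 2 rose and 8 fell, with RAD51AP1 lower by 1.03 ± 0.0904. Of 12 end joining genes 1 rose and 4 fell, of 16 Fanconi anemia genes 0 rose and 2 fell, and of 15 checkpoint genes 0 rose and 3 fell. Of 31 p53 targets, 7 rose and 3 fell, with the death receptor gene FAS higher by 0.79 ± 0.0843 and SESN2 by 0.50 ± 0.0706. Immediate early genes had a median of 0.15 but a mean of -0.27, and replication-dependent histones a median of -0.24 with the list test pointing upward; neither was called.

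The remaining lists were not called on day 3. Of 23 cleavage and polyadenylation factors 1 rose and 2 fell, and of 22 looping and transcription elongation factors 0 rose and 3 fell, at medians of -0.04 and -0.06. Interferon-stimulated genes fell in 9 of 24 cases and rose in 1, SAMD9, at a median of -0.39. Of 30 nuclear-encoded oxidative phosphorylation genes 0 rose and 9 fell, and of 13 mitochondrially encoded transcripts 0 rose and 4 fell. Mitosis genes rose in 2 of 32 cases and fell in 3, heat shock genes rose in 4 of 15 cases and fell in 4, and senescence genes rose in 1 of 15 cases and fell in 5. Of 6 genes of cytosolic DNA sensing 1 rose and 2 fell, at a median of -0.04 and a mean of 0.02. Adjusted p for these lists was at least 0.2 (camera, Benjamini-Hochberg).

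On day 6 the knockout cells again had less RNA of inflammatory factors. CXCL8 fell by 7.73 ± 0.14, and C1QTNF1 by 7.17 ± 0.262. C1QTNF1 had a knockout mean of 0.21 CPM, where the standard error also understates the counting error. CD274, which encodes the immune checkpoint ligand PD-L1, rose by 4.43 ± 0.0838, from 6.68 ± 0.372 to 144 ± 0.305 CPM (SD, n = 3). The keratin-associated protein gene KRTAP2-3 rose by 5.42 ± 0.126, the keratin gene KRT34 by 4.33 ± 0.226, SYT7, a calcium sensor of vesicle fusion, by 5.21 ± 0.258, and NTF3, which encodes neurotrophin 3, by 4.68 ± 0.244. ZNF185, WNK4 and G0S2, all higher on day 3 too, rose by 4.78 ± 0.0835, 4.48 ± 0.122 and 3.85 ± 0.0806. APCDD1L, APBA1, SLAMF7 and NIPAL4 rose by 4.37 ± 0.181, 3.98 ± 0.16, 3.74 ± 0.157 and 3.58 ± 0.0951.

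Several genes had no count in the 3 knockout libraries on day 6. TIMP3, at 4529 ± 99.8 counts in controls (SD, n = 3), was at least 3400-fold lower, and EMC10 at least 937-fold. PTGIS, the prostacyclin synthase gene, was at least 315-fold lower, GABRE, a GABA receptor subunit gene, at least 209-fold, ZNF544 at least 198-fold and DPYSL4 at least 190-fold. With 1 or 2 knockout counts, the ratio of control to knockout was 810 for the collagen gene COL11A1 (95% counting interval 224 to 6690), 697 for ABCA8 (125 to 27600), 543 for VIT (97.1 to 21500) and 254 for the serotonin receptor gene HTR7 (70.1 to 2100). Adjusted p for these 24 genes was at most 3.12e-13 (edgeR, Benjamini-Hochberg).

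**Figure D4:**
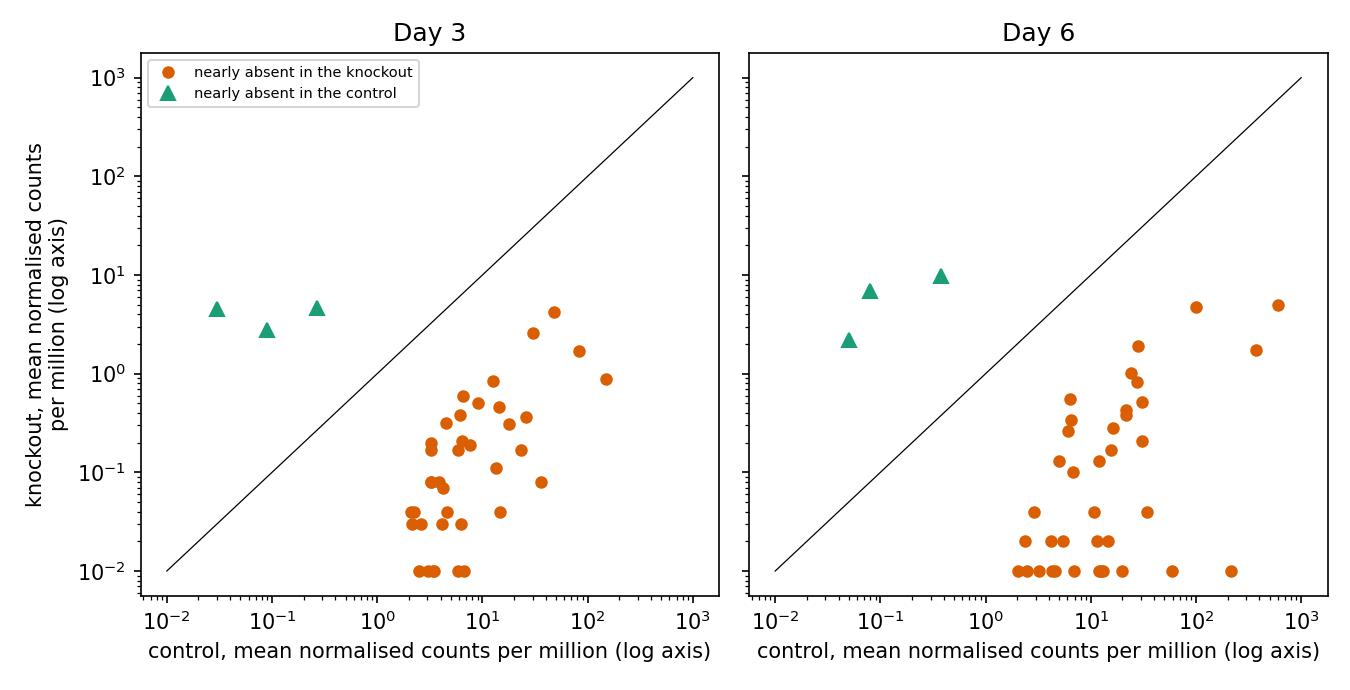
Mean CPM (logarithmic axis, values of 0 drawn at 0.01) in control and knockout libraries on each day for the 38 genes nearly absent from the knockout and the 3 nearly absent from the control on both days. Points are means of 3 libraries.

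Changes were called for 9679 genes on day 6, 4574 higher and 5105 lower, and 3212 of them at least 2-fold. These libraries had fewer detected genes and lower TMM factors, and scaling by library totals alone moved the median of all genes by -0.37 and gave 2229 higher and 8645 lower. Limma-trend on log2(TPM + 0.5) gave 2177 and 7085. Of the genes called on both days, 1468 were higher on both, against 633.2 for independent lists, 1700 lower on both, against 949.2, and 691 opposite, against 1557.2. Across genes, which are not independent replicates, the log2 fold changes of the days had a Pearson correlation of 0.591 and a Spearman correlation of 0.423.

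Again 9 of 29 lists were called on day 6, where the knockout libraries had a mean TMM factor of 0.762. NF-kB targets fell in 13 of 18 cases and rose in 4, at a median of -1.58, with CCL2, a monocyte chemokine gene, at -4.12 ± 0.104, IL6 at -3.67 ± 0.14 and IL1B at -2.09 ± 0.0712 (camera, Benjamini-Hochberg adjusted p = 6.12e-10, and adjusted p = 0.0173 with an estimated correlation). Integrated stress response genes rose in 18 of 22 cases and fell in 4, at a median of 0.94. ASNS, the asparagine synthetase gene, rose by 2.90 ± 0.0883, TRIB3 by 2.59 ± 0.0745, PCK2 by 2.26 ± 0.0691 and SLC7A5 by 1.81 ± 0.0533 (camera, Benjamini-Hochberg adjusted p = 6.09e-11, and adjusted p = 0.00216 with an estimated correlation). YAP and TGF-beta targets rose in 15 of 19 cases and fell in 4, at a median of 1.13. CCN1, a matricellular protein gene, rose by 3.18 ± 0.0553 and F3, the tissue factor gene, by 2.39 ± 0.0569, while the cell cycle inhibitor gene CDKN2B fell by 2.51 ± 0.0778 (camera, Benjamini-Hochberg adjusted p = 5.08e-13, and adjusted p = 0.0146 with an estimated correlation). The medians of these 3 lists with library totals alone were -1.95, 0.57 and 0.76.

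The remaining 6 calls of day 6 were lost with an estimated correlation. Mitosis genes rose in 25 of 32 cases and fell in 1, at a median of 0.60, with UBE2C, BUB1 and AURKB higher by 1.18 ± 0.0748, 1.09 ± 0.0716 and 1.25 ± 0.0844 (camera, Benjamini-Hochberg adjusted p = 3.61e-05, and adjusted p = 0.265 with an estimated correlation). Matrix genes rose in 17 of 26 cases and fell in 5, at a median of 0.69, with COL4A1, COL4A2 and TGFBI higher by 2.08 ± 0.0533, 1.54 ± 0.0596 and 1.76 ± 0.0525 (camera, Benjamini-Hochberg adjusted p = 5.17e-06, and adjusted p = 0.296 with an estimated correlation). Immediate early genes rose in 13 of 21 cases and fell in 5, at a median of 0.70, with KLF6 and DUSP1 higher by 2.52 ± 0.0591 and 2.18 ± 0.0535 and IER3 lower by 3.09 ± 0.0733 (camera, Benjamini-Hochberg adjusted p = 0.000425, and adjusted p = 0.265 with an estimated correlation). Interferon-stimulated genes fell in 18 of 24 cases and rose in 3, at a median of -1.13, with IFIT1, IFIT2, IFIT3 and PARP14 lower by 2.60 ± 0.207, 2.78 ± 0.204, 1.70 ± 0.126 and 1.54 ± 0.0908 (camera, Benjamini-Hochberg adjusted p = 0.00252, and adjusted p = 0.296 with an estimated correlation). Unfolded protein response genes fell in 13 of 18 cases and rose in 3, at a median of -0.53, with DNAJC3 and HYOU1 lower by 1.56 ± 0.0718 and 1.16 ± 0.0595 (camera, Benjamini-Hochberg adjusted p = 0.00233, and adjusted p = 0.207 with an estimated correlation). Ribosomal protein genes rose in 44 of 51 cases and fell in 0, at a median of 0.32 that became -0.05 with library totals alone, when 6 rose and 16 fell; RPSA and RPLP0 rose by 0.69 ± 0.0506 and 0.59 ± 0.0505 (camera, Benjamini-Hochberg adjusted p = 0.000384, and adjusted p = 0.331 with an estimated correlation). With library totals alone mitosis genes rose in 18 cases and fell in 4, at a median of 0.22, matrix genes in 14 and 8, at 0.32, and immediate early genes in 12 and 6, at 0.33. Interferon-stimulated genes then rose in 1 case and fell in 21, and unfolded protein response genes in 0 and 15. Adjusted over the list alone, the counts higher and lower of these 6 lists differed from those above only for ribosomal proteins, at 46 and 0.

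Among lists not called on day 6, 17 of 31 p53 targets rose and 9 fell, with FAS higher by 1.91 ± 0.0936 and SESN2 by 1.26 ± 0.0715, whereas with library totals alone 9 rose and 14 fell (camera, Benjamini-Hochberg adjusted p = 0.0708). Of 21 cholesterol synthesis genes 13 rose and 4 fell, at a median of 0.36 that became -0.01 with library totals alone, and INSIG1 rose by 1.05 ± 0.0803 (camera, Benjamini-Hochberg adjusted p = 0.157). Of 18 genes of the MRN complex and break signalling 2 rose and 11 fell, with MAD2L2 higher by 0.69 ± 0.0971 and TP53BP1 lower by 0.37 ± 0.0587. Of 12 end joining genes 5 rose and 4 fell, and DCLRE1C, the Artemis nuclease gene, and XRCC4 were lower by 1.06 ± 0.114 and 1.08 ± 0.118. Of 24 homologous recombination genes 8 rose and 7 fell, and of 16 Fanconi anemia genes 6 rose and 3 fell. With library totals alone 1 rose and 16 fell of the MRN and break signalling genes, 1 and 7 of the end joining genes, 1 and 12 of the homologous recombination genes and 3 and 7 of the Fanconi anemia genes, whose median went from 0.20 to -0.17.

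On day 6, 6 of 23 cleavage and polyadenylation factors rose and 12 fell, at a median of -0.20, and 8 of 22 looping and transcription elongation factors rose and 8 fell, at -0.03 (camera, Benjamini-Hochberg adjusted p = 0.71 and 0.935). Heat shock genes fell in 8 of 15 cases and rose in 2, at a median of -0.35 (camera, Benjamini-Hochberg adjusted p = 0.0511). Of 36 DNA replication genes 10 rose and 13 fell, of 15 checkpoint genes 3 rose and 3 fell, and of 10 tested histone genes 1 rose and 4 fell. Glycolysis and hypoxia genes rose in 11 of 25 cases and fell in 9, with a median of 0.09 and a mean of -0.17, but in 5 and 17 with library totals alone, and in 11 and 11 after GC and length correction. Oxidative phosphorylation genes rose in 9 of 30 cases and fell in 5, but in 3 and 23 with library totals alone. Mitochondrially encoded transcripts rose in 2 of 13 cases and fell in 5, with a median of 0.24 while the list test pointed downward, and their share of the counts was uneven within groups, at 6.89%, 4.03% and 4.05% in controls and 2.997%, 4.001% and 5.80% in knockouts. Senescence genes rose in 5 of 15 cases and fell in 5, with a median of -0.13 while the list test pointed upward, and 4 of 6 genes of cytosolic DNA sensing rose and 2 fell. With library totals alone the numbers higher and lower were 2 and 19 for polyadenylation factors, 3 and 15 for looping and elongation factors, 1 and 13 for heat shock, 4 and 22 for DNA replication, 2 and 10 for checkpoint genes, 1 and 6 for histones, 2 and 6 for mitochondrially encoded transcripts, 4 and 9 for senescence and 2 and 3 for DNA sensing.

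No marker list with enough tested members was called on either day. Of 5 tested pigment epithelium markers, the lineage of RPE1, 0 rose and 2 fell on day 3 and 0 rose and 4 fell on day 6, with OTX2, an eye transcription factor gene, lower by 0.31 ± 0.0937 and 1.51 ± 0.0922 (camera, Benjamini-Hochberg adjusted p = 0.723 and 0.199). The day 3 call of OTX2 was lost with limma-trend on log2(TPM + 0.5) (-0.11), without day 3 control 2 (-0.25) and without day 3 knockout 2 (-0.28). The median of the list on day 6 was -0.54, and -0.91 with library totals alone. Of 9 fibroblast markers 3 rose and 3 fell on day 3 and 2 rose and 5 fell on day 6 (camera, Benjamini-Hochberg adjusted p = 0.738 and 0.523), at a day 6 median of -0.75, or -1.13 with library totals alone. The remaining 3 marker lists had too few tested members for a list test. The keratin-rich list held CLDN4 alone, which rose by 1.25 ± 0.41 and 1.47 ± 0.362, the day 3 call being lost with limma-trend on log2(TPM + 0.5) (0.36), without day 3 control 3 (0.93) and without day 3 knockout 1 (1.06). Of the neural-like list, TUBB2B rose by 0.73 ± 0.137 and 1.05 ± 0.146, and GAP43 had a day 3 value of -0.70 ± 0.445 that did not pass and fell by 1.54 ± 0.496 on day 6, a call lost without day 6 control 2 (-1.26). The blood list held CD74 alone, lower at a ratio of control to knockout of 27.5 (95% counting interval 9.11 to 136) on day 3 and at least 16.5-fold on day 6, from 22 ± 5.2 counts in controls (SD, n = 3).

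Whether the knockout effect differed between days was tested in the same model. Differences were ranked among called genes with a symbol and a mean of at least 5 CPM over the 12 libraries. Among these, the effect on day 6 exceeded that on day 3 most for KRTAP2-3, by 5.57 ± 0.185, RPSAP52 by 3.38 ± 0.222, SH2D5 by 3.37 ± 0.16, CD274 by 3.03 ± 0.121 and TMEM158 by 2.94 ± 0.118. It was lower on day 6 for HES1, a Notch target gene, at -4.16 ± 0.248, and for the potassium channel gene KCNJ2, at -4.12 ± 0.361. TIMP3 and EMC10 also passed in that direction, but with counts near 0 in the knockout their fitted sizes rest on the prior count. PTGIS passed as well, at -4.79, with knockout counts near 0. Its call was lost at fitted differences of about the same size, -4.838 to -4.764, without a count filter, with either replicate block, without any 1 of the day 6 knockouts and without day 6 control 1 and knockout 3 together (edgeR, Benjamini-Hochberg adjusted p from 0.0522 to 0.0776). It was also lost at -3.515 with DESeq2 (Benjamini-Hochberg adjusted p = 0.0548) and at -2.259 without day 3 knockout 1 (edgeR, Benjamini-Hochberg adjusted p = 1). CDKN1A rose more on day 6, by 1.38 ± 0.0764. Adjusted p for these genes was at most 0.0399 (edgeR, Benjamini-Hochberg). The difference passed for 7185 genes, 3774 positive and 3411 negative. Library totals alone moved the median by -0.36 and gave 1506 and 6907, and limma-trend on log2(TPM + 0.5) gave 992 and 5647.

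Of 8 lists called for the difference between days, 2 held with an estimated correlation. Cholesterol synthesis genes had a more positive effect on day 6 in 16 of 21 cases, at a median of 0.66, with INSIG1 at 2.13 ± 0.108 (camera, Benjamini-Hochberg adjusted p = 7.75e-07, and adjusted p = 0.00753 with an estimated correlation). In the integrated stress response, 16 of 22 genes were more positive and 5 more negative on day 6, with ASNS at 2.28 ± 0.117 and DDIT4 at -3.09 ± 0.0962 (camera, Benjamini-Hochberg adjusted p = 8.58e-07, and adjusted p = 0.00753 with an estimated correlation). All 51 ribosomal protein genes were more positive on day 6, RPSA by 0.77 ± 0.0713 and RPLP0 by 0.71 ± 0.0713, as were 25 of 32 mitosis genes, AURKB by 1.44 ± 0.107 and BUB1 by 1.15 ± 0.0928. Immediate early genes were more positive in 13 of 21 cases and more negative in 4, KLF6 by 2.05 ± 0.0808 and DUSP1 by 1.85 ± 0.0743, and YAP and TGF-beta targets more positive in 11 of 19 and more negative in 5, CCN1 by 2.59 ± 0.0733. These 4 lists were lost with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0935 with an estimated correlation for each). Interferon-stimulated genes were more negative in 14 of 24 cases and more positive in 1, PARP14 by -1.42 ± 0.126 and IFIT2 by -2.17 ± 0.274 (camera, Benjamini-Hochberg adjusted p = 0.0018, and adjusted p = 0.326 with an estimated correlation). Heat shock genes were more negative in 8 of 15 cases and more positive in 3, HSPH1 by -1.40 ± 0.0983 and HSPA1A, which has a near-identical copy, by -1.39 ± 0.0864 (camera, Benjamini-Hochberg adjusted p = 0.00921, and adjusted p = 0.154 with an estimated correlation). With library totals alone 20 of the 51 ribosomal protein genes were more positive and 0 more negative, at a median of 0.13 against 0.50. The counts more positive and more negative were then 15 and 2 for mitosis genes, 11 and 7 for immediate early genes, 9 and 7 for YAP and TGF-beta targets, 11 and 2 for cholesterol synthesis, at a median of 0.301, 13 and 5 for the integrated stress response, 0 and 17 for interferon-stimulated genes and 1 and 12 for heat shock genes. Adjusted over the list alone, the counts of the 8 lists differed from those first given only for mitosis genes, at 26 more positive.

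From day 3 to day 6 the control cells showed lower RNA of cell division genes and higher RNA of hypoxia-responsive genes. CA9, which encodes a carbonic anhydrase, rose by 6.81 ± 0.0907, SLC14A1, a urea transporter gene, by 6.13 ± 0.153, FER1L4 by 5.48 ± 0.216, PRSS33 by 4.93 ± 0.129 and PPFIA4 by 4.84 ± 0.119. SH2D5, the replication factor gene MCM10, PSMC3IP, SAPCD2 and MROH6 fell, at -3.03 ± 0.124, -3.02 ± 0.104, -2.996 ± 0.135, -2.97 ± 0.0975 and -2.96 ± 0.197. All 32 mitosis genes fell, at a median of -2.30, PLK1 by 2.82 ± 0.0684 and AURKA by 2.69 ± 0.0643, as did all 36 DNA replication genes, at a median of -2.14, MCM4 by 2.52 ± 0.0573 and MCM3 by 2.18 ± 0.0568. Homologous recombination genes fell in 21 of 24 cases and rose in 0, BRCA1 by 2.60 ± 0.101 and BRIP1 by 2.33 ± 0.0895. All 25 glycolysis and hypoxia genes rose, at a median of 1.66, NDRG1 by 4.37 ± 0.0727 and BNIP3 by 2.31 ± 0.0524. Matrix genes rose in 25 of 26 cases and fell in 0, LAMA4 by 2.64 ± 0.0605 and SPARC by 1.69 ± 0.0503. Fibroblast markers rose in 6 of 9 cases and fell in 1 (camera, Benjamini-Hochberg adjusted p = 0.0015, and adjusted p = 0.0239 with an estimated correlation). These 6 lists were called at an adjusted p of 0.0015 or less, and at 0.0259 or less with an estimated correlation (camera, Benjamini-Hochberg). In controls 18 lists were called and 13 held with an estimated correlation.

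In the knockout cells CA9 rose from day 3 to day 6 by 5.69 ± 0.0801, SLC14A1 by 5.68 ± 0.124, the immediate early gene EGR1 by 5.10 ± 0.102, PLAT, the tissue plasminogen activator gene, by 4.85 ± 0.061 and HR by 4.63 ± 0.221. DIO2, the cell cycle genes E2F2, CCNE2 and CDC25A, and FAM111B fell by 4.41 ± 0.221, 4.39 ± 0.197, 4.15 ± 0.186, 3.95 ± 0.166 and 4.07 ± 0.113. DNA replication genes fell in 36 of 36 cases, at a median of -2.05, and mitosis genes in 32 of 32, at -1.69. Ribosomal protein genes rose in 51 of 51 cases at a median of 0.74, and immediate early genes in 19 of 21 at 1.28. Scaled by library totals alone, ribosomal protein genes rose in 26 cases and fell in 2, at a median of 0.14, and immediate early genes in 14 and 3, at 0.69, while all DNA replication and mitosis genes still fell. In the knockout 16 lists were called and 15 held with an estimated correlation. Over time 9947 genes changed in controls, 4979 higher and 4968 lower, and 10634 in the knockout, 5195 higher and 5439 lower (edgeR, Benjamini-Hochberg adjustment). Library totals alone moved the medians by -0.23 and -0.59 and gave 3430 higher and 6774 lower in controls and 2122 and 9489 in the knockout, where limma-trend on log2(TPM + 0.5) gave 2126 and 8200. In the same direction, 3365 genes rose and 3468 fell in both genotypes, against 1733.2 and 1810.6 for independent lists.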

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

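The tests of nearly absent genes, of GPR83 and of library composition were chosen only after those results had been seen. The difference between the knockout effects of day 6 and day 3 was part of the design, and 87 of 121 named genes passed it, 50 with a more positive and 37 with a more negative effect on day 6. Over all 14924 genes 48.1% passed, and some of the named genes were chosen for large differences, so the share among them is not a measure of breadth. Of the 87, library totals alone called 41 more positive and 38 more negative, and limma-trend on log2(TPM + 0.5) called 34 and 37. Values below are log2 differences, day 6 minus day 3, with TMM factors, each at an adjusted p under 0.05 (edgeR, Benjamini-Hochberg).

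The larger positive differences were those of KRTAP2-3 5.57, SYT7 5.36, KRT34 4.67, RPSAP52 3.38, SH2D5 3.37, CD274 3.03, TMEM158 2.94, NIPAL4 2.68, CCN1 2.59, ZNF185 2.38, ASNS 2.28, APBA1 2.26 and INSIG1 2.13. Further positive differences were KLF6 2.05, WNK4 2.05, SLAMF7 1.96, DUSP1 1.85, F3 1.84, TRIB3 1.80, APCDD1L 1.80, IL1B 1.64, PCK2 1.60, AURKB 1.44, CDKN1A 1.38, SLC7A5 1.23, SERPINB2 1.204 and UBE2C 1.17. Positive differences of middle size were BUB1 1.15, STC2 1.12, FAS 1.12, G0S2 1.00, TAF1D 0.94, MAD2L2 0.88, RPSA 0.77, SESN2 0.76, COL4A1 0.76, COL4A2 0.72, RPLP0 0.71 and RAD51AP1 0.65. The smaller positive differences were RPL10 0.64, TGFB2 0.61, DHCR7 0.57, ENO2 0.56, RPL19 0.52, TGFBI 0.49, KRT81 0.47, RBBP8 0.46, TAGLN 0.38, ENDOD1 0.23 and TPI1 0.17. With library totals alone TPI1 was called more negative and ENDOD1 was negative and not called, and RAD51AP1, DHCR7, RPL19, TGFBI, KRT81, RBBP8 and TAGLN were positive and not called, so these 9 differences depend on the scaling. Limma-trend on log2(TPM + 0.5) did not call them more positive either, nor APCDD1L, TAF1D, SESN2, COL4A1, RPL10, TGFB2 and ENO2, and among the negative differences it did not call IGFBP5. Negative differences of small size were MCM3 -0.28, FEN1 -0.35, TP53BP1 -0.37, IGFBP5 -0.51, HYOU1 -0.60, PTGFRN -0.63, MDM2 -0.65, PLXNA4 -0.68, ANKRD49 -0.72, VLDLR -0.75 and DCLRE1C -0.75. Further negative differences were XRCC4 -0.76, IFIT3 -0.87, SAMD9 -0.91, SRSF8 -0.93, ACTA2 -1.02, CA9 -1.13, OTX2 -1.20, DNAJC3 -1.27, C3 -1.32, HSPA1A -1.39, HSPH1 -1.40 and PARP14 -1.42. The larger negative differences were CCL2 -1.59, IFIT1 -1.76, CDKN2B -2.04, IFIT2 -2.17, DDIT4 -3.09, C1QTNF1 -3.16, KCNJ2 -4.12 and HES1 -4.16. C1QTNF1 was at 0.20 and 0.21 CPM in the knockout on the 2 days, while controls went from 3.22 to 30.89 CPM. Its difference thus follows the rise in controls. For HTR7 -2.36, ABCA8 -3.63, COL11A1 -3.67, EMC10 -4.65, PTGIS -4.79 and TIMP3 -8.08, counts near 0 in the knockout make the fitted values depend on the prior count. Control means of each of these genes were higher on day 6, those of TIMP3 going from 23.44 to 213.9 CPM. The calls of PTGIS, HTR7, ABCA8 and COL11A1 were lost in some alternatives, including the removal of single libraries, with a negative value in each, and the same held for the smaller differences of FEN1 and ANKRD49. The effects on 8 lists differed as well, with medians of 1.02 for immediate early genes, 0.94 for the integrated stress response, 0.66 for cholesterol synthesis, 0.62 for mitosis, 0.50 for ribosomal proteins, 0.45 for YAP and TGF-beta targets, -0.33 for the heat shock response and -0.70 for interferon-stimulated genes. In the same order, these medians were with library totals alone 0.658, 0.571, 0.301, 0.256, 0.13, 0.08, -0.694 and -1.065.

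When the libraries of a day were divided in the other possible ways, the highest number of changed genes was 0 on day 3 and 0 on day 6, against the real 4841 and 9679, and 0 for the changes with time, against 9947 and 10634. Only 1 of the 10 divisions, the real 1, reached each of these counts, which is too few for a p under 0.05. Every other division mixes both real groups, which widens the spread within its groups and lowers such counts. It also carries part of the real difference. For the difference between days, 2 of 100 divisions had at least 7185 genes, and the highest other count, 9144, came from exchanging the genotype labels on 1 day only. For the lists, 5 of 10 divisions, the real 1 among them, reached 9 on day 3, where another division gave 10. The number of lists called on day 3 thus did not stand out from the other divisions. On day 6, 1 of 10 reached 9, where the highest other was 8, and 10 divisions are too few for a p under 0.05. For the difference between days 35 of 100 divisions had at least 8 lists, with a highest value of 11, so chance was not excluded for the number of lists. Divisions that keep the real labels on 1 day carry part of the knockout effect, so they are not a comparison without any change. For weighted length, 2 of 10 divisions had 1 gene on day 3, and 1 of 10 reached 518 on day 6, where the highest other was 1.

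On both days 38 genes were nearly absent from the knockout, among them TIMP3, COL11A1, CXCL2, CXCL3 and C3, against 3 nearly absent from the control, GPR83, ADM2 and NTF3. Of 200 divisions within the days 1, the real 1, reached 38 and the highest other was 1, but every other division puts control libraries into the low group and the limits were set after the values were seen, so this count does not decide about chance. In the test over all 14924 genes each of the 38 was lower on both days, at an adjusted p of at most 5.71e-08 on day 3 and 2.5e-08 on day 6 (edgeR, Benjamini-Hochberg). Tested genes within 200 kb of the 38, themselves left out, had a median log2 change of -0.066 on day 3. Of these 209 neighbours 52 were lower and 17 higher, against 2775 and 2066 of all 14924 genes. The median argues against loss of the surrounding segment for most of these neighbours. Yet lower calls made up a larger share of them than of all genes, and higher calls a smaller share. The median was pooled over all places, so loss at single places was not excluded. Some of the 38 lie near each other, such as ZNF585A and ZNF585B, and their joint loss was not counted. Origin of the knockout cells from few founder cells could explain the 38 genes and could not be told from an effect of the deleted site, as no control of known matched origin was analysed here. This limit holds for every other difference between knockout and control cells reported here, on either day. Variation of the definition in 9 settings of its limits, each with TMM and with library totals alone, gave 14 to 112 such genes in the knockout and 0 to 21 in the control.

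GPR83, beyond the 3′ end of MRE11, rose from near 0 on both days, as did ADM2, which went further on day 6, from 0.08 to 6.93 CPM against 0.05 to 2.22 for GPR83. Of 42737 silent genes, those under 0.1 CPM in the controls, 0.00468%, GPR83 and ADM2, reached 2 CPM in the knockout on both days. A general switching on of silent genes to that level thus did not account for the rise of GPR83. The limit of 2 CPM was set after the values were seen, and rises to lower levels were not examined. Transcription reading on from MRE11 into GPR83 may fit, since their changes from day 3 to day 6 in the knockout differed by 0.128 ± 0.281 (log2, standard error). Many other genes fell with time, so this match is weak evidence, and reads joining the genes were not analysed here.

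The breadth of the day 6 comparison was weighed against 3 explanations. Without the 100 most abundant genes 9633 changed. TMM factors already limit the weight of such genes, so this count could not test whether abundant genes took up the counts. GC content and transcript length did not account for the breadth, as 10082 genes changed after their correction. A composition of the libraries set by the knockout state itself might be involved, with a mean TMM factor of 0.762 in day 6 knockout libraries. Counts without an added standard cannot tell this from a change in total RNA. Nor can it be told from a culture or RNA quality difference of the same libraries, or from the origin of the knockout cells. Across genes the log2 fold change rose with mean expression on day 6, at a Spearman correlation of 0.327, against 0.061 on day 3.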

How the results depend on the processing

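Correction for GC content and length, leaving out the 100 most abundant genes and leaving out day 6 control 1 with day 6 knockout 3 were tests chosen only after the results had been seen. Genes changed on day 3, 4841 in the design as fixed, numbered 3037 with limma-trend on log2(TPM + 0.5), 2099 with glmTreat against 1.2-fold and 920 at a log2 fold change of at least 1. That last limit left 3212 genes on day 6, 2106 for the difference between days, 3157 over time in controls and 3860 over time in the knockout. The MRE11 fall on day 6, at -0.37, was not called with DESeq2 (-0.342), limma-voom (-0.38), GC and length correction (-0.22) or without day 6 control 1 and knockout 3 (-0.247), the libraries farthest from the others of their groups. It was called and larger with library totals alone (-0.744) and limma-trend on log2(TPM + 0.5) (-0.891). Leaving out single libraries gave -0.547 to -0.281, and the call was lost without day 6 control 1 (-0.315), control 2 (-0.349), knockout 1 (-0.281) or knockout 3 (-0.304); the cause was not tested. The MRE11 fall on day 3 was kept in every setting. Lists called numbered 4 on day 3, 3 on day 6 and 2 for the difference with an estimated correlation, and 22, 23 and 22 with fry, which asks whether a list changed at all and not whether it changed more than other genes. Genes with a changed weighted length on day 3, 1 in the design as fixed, numbered 5 with at least 20 expected counts, 0 with a replicate block within day and 1 to 5 without single libraries, reaching 5 without day 3 knockout 2, 3 without day 3 knockout 3 or day 6 knockout 1, and 2 without day 3 knockout 1, day 6 control 2, day 6 knockout 2 or day 6 knockout 3. On day 6 their number was 220 with the replicate block and 265 to 450 without single libraries, with 265 without day 6 control 1 and 326 without control 2, and the cause was not tested. The replicate numbers did not pair the libraries. Deviations from the group means had a mean correlation of 0.009 between same-number libraries of a day. Of 6581 alternative values run for 260 results of 143 named genes other than MRE11, 6491 kept their call, 83 were weaker and 7 changed sign. Those 7 were differences between days, of TPI1 (-0.194) and ENDOD1 (-0.139) with library totals alone and of TPI1 (-0.255), ENDOD1 (-0.228), RBBP8 (-0.065), TAGLN (-0.061) and TGFB2 (-0.013) with limma-trend on log2(TPM + 0.5), and both TPI1 values passed in the new direction. Weaker values concerned NBN, MCM4, SESN3, RBBP8, OTX2 and CLDN4 on day 3, ANKRD49 and GAP43 on day 6, and for the difference between days TPI1, ENDOD1, TAGLN, RBBP8, KRT81, TGFBI, RPL19, RPL10, DHCR7, RAD51AP1, ENO2, COL4A1, SESN2, TAF1D, APCDD1L, IGFBP5, FEN1, ANKRD49, HTR7, ABCA8, COL11A1 and PTGIS.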

Other observations

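No test in this part was chosen after a result was seen beyond those already named. Sequencing in which the joined reads between MRE11 and GPR83 can be examined would separate transcription reading on from a start within GPR83. Reads at the ends of MRE11 transcripts would show whether the proximal site was removed, which weighted lengths of the whole gene do not. A second set of knockout cells of separate origin would tell genes lost with the founder cells from genes that depend on the deleted site, and TIMP3, EMC10 and ZNF544 would be the clearest to follow. An added RNA standard would show whether total RNA differed in the knockout on day 6.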
